A study of Arabidopsis thaliana with 4 samples.

How the data were processed

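Silique RNA of Arabidopsis thaliana Col-0 was measured in 4 libraries, 1 for each of 4 age classes. Per the labels, total RNA was extracted with Trizol, treated with DNase, column-purified, made into libraries with the TruSeq RNA kit in its second version and sequenced from both ends on an Illumina HiSeq. That kit does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the TAIR10 build, with versions not given in the sources used here. The deposited files give the authors' FPKM, 1 value per Cufflinks locus, repeated for every gene assigned to that locus. The 30915 rows of each file reduce to 29971 loci, of which 29153 name 1 gene and 818 name several. Genes in a shared locus, near-identical family members included, carry 1 joint or uncertain value.

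Groups were taken from each sample's developmental stage label. The growth protocol gives other limits for some stages, such as a first day of 1 for stage 1, and these were not used. Gene names and transcript lengths came from the RefSeq annotation of TAIR10.1, in which 28733 single-gene loci were found by identifier, all overlapping the gene of that name, while coordinates in the text are those of the deposited files. The files hold loci of chromosomes 1 to 5.

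FPKM values are not counts, so no count test was run, and with 1 library per stage there is no replicate error and no p-value. A locus was counted as higher or lower when log2(FPKM + 1) differed by at least 1 and the higher FPKM was at least 1. A fold on this scale understates the change of low genes. The planned rule also asked for an estimate status and for confidence intervals that did not overlap. The files used here have neither, so these 2 criteria were not applied. The plan kept loci listed at 0 in 1 library. Loci listed at exactly 0 in either library have no readable fold and were left out of counts and medians, a departure from the plan made after seeing that abundant genes were among them; the closing section gives the counts with them. A gene peaked in a stage when it was at least 2-fold above each of the other 3 libraries. No fold or limit is given against a value listed at 0.

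Gene groups came from 22 lists of 397 entries, fixed before the data were examined, as were the 2-fold and FPKM limits of the counting rule. Of these, 20 entries have no row in the files used and were not analysed here. The lists cover storage proteins, oil bodies, fatty acid and oil synthesis, LEA and desiccation, maturation regulators, endosperm, embryo patterning, flavonoids, seed coat mucilage, fruit patterning and dehiscence, secondary wall and lignin, photosynthesis, cell cycle, expansins, senescence, abscisic acid, gibberellin, heat shock, pollen, floral organs and nectary, tapetum, and reference genes. The change of a list is the median over members, given when at least 3 members were readable. Its percentile among 10000 random lists of the same size, drawn from protein-coding loci in 20 bins of mean expression, is a description of these libraries and not a test. The text names the 10 largest increases and decreases per comparison among single protein-coding loci with FPKM of at least 10 in the higher library, members of the lists with preference for high values or large changes, the 10 most abundant genes of a library and the 5 most abundant peaking genes of a stage.

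Depth was estimated from the low values. Over 2643 loci with 1 transcript of more than 1500 bases and unchanged ends, FPKM times transcript length less 180 bases fell on whole multiples of 1 fragment, within a tolerance of 0.2 fragments, for 69.1% to 77.5% of the values under 3.5 fragments. There were 236 to 271 such values per library. The step and the 180 bases were chosen on low values of these same loci, so the share is no independent check. The share that evenly spread values would give was not computed. The resulting fragment numbers assume the plain FPKM formula; if libraries were also scaled to each other, they give relative depth. In simulated libraries with 200 changed loci of 25884, made for stage 2 against stage 1, the counting rule recovered 15.0% of changes of exactly 2-fold and 100.0% of changes of 3-, 4- and 8-fold, and called 0 unchanged loci. With 1 added to FPKM, an exact 2-fold change falls short of the limit, so only counting error can bring it over. The 15.0% is therefore no measure of sensitivity. The changed loci were drawn from those with a median FPKM of at least 5. Recovery at lower FPKM was not simulated, and there the added 1 hides larger folds. These simulations hold counting error alone and no spread between fruits, so they give no rate of false calls for the stage comparisons. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives were other pseudocounts (0.1 and 5), FPKM minimums (none and 5), 4 rescalings of the libraries, a 4-fold limit, including loci listed at 0 as planned and, chosen after seeing the data, leaving out loci under 300 bases. Of the rescalings, the one over loci of 300 bases or more was chosen after seeing the data.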

Results

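Messenger RNA was profiled in developing fruits (siliques, the pods that enclose the seeds) of the Arabidopsis thaliana accession Col-0. Fruits were collected at 4 ages, counted in days after the flower opened (anthesis). Stage 1 covered days 0 to 5, stage 2 days 6 to 10, stage 3 days 11 to 15 and stage 4 days 16 to 20. Each stage was represented by 1 library, so the differences below have no replicate check and no p-value is given. They describe these 4 libraries. The deposited values were FPKM, fragment numbers scaled to transcript length and to the size of the library, for 29971 loci of the TAIR10 gene models. Read totals were not part of the values. The smallest FPKM values fell on steps that correspond, under the plain FPKM formula, to about 68.1, 100.7, 67.1 and 59.3 M (mega, as in megabases) fragments in stages 1 to 4. A single fragment on a transcript of 1500 bases was then worth 0.0111, 0.00752, 0.0113 and 0.0128 FPKM. Bringing the libraries to a common median ratio took factors of only 0.985 to 1.03. They may thus have been scaled to each other already, and the fragment numbers then give relative depth only. Between 16356 loci (stage 4) and 17020 loci (stage 1) reached FPKM 1.

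The question asked of the series was how the transcriptome of the fruit changes from fertilisation to seed maturation. Neighbouring stages resembled each other most. Across loci, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) was 0.972 between stages 3 and 4, 0.919 between stages 2 and 3, and 0.916 between stages 1 and 2. It was lowest between stages 1 and 4, at 0.821. The most abundant transcripts also changed in kind. Photosynthetic and lipid-transfer transcripts were among the most abundant in stage 1, with RBCS1A, the small subunit of the carbon-fixing enzyme Rubisco, at 14172 FPKM and the lipid transfer protein gene LP1 at 11558 FPKM. Seed protein transcripts were among the most abundant in stage 4, with the 2S albumin SESA2 at 27189 FPKM and the oil body protein OLEO1 at 15738 FPKM. The seed storage list held 0.00126% of the FPKM sum in stage 1, 0.206% in stage 2, 3.36% in stage 3 and 6.45% in stage 4. Of its 11 members, 4 were listed at 0 in stage 3 and 5 in stage 4, among them SESA3, CRA1 and CRC, so the shares of these stages leave them out and are not comparable with those of stages 1 and 2. A single very short locus, AT2G01021 (chromosome 2, 6571 to 6672), took 78.3%, 63.1%, 45.0% and 6.65% of the FPKM sum in stages 1 to 4. Without loci under 300 bases, an alternative chosen after seeing the data, the storage list held 0.00589%, 0.558%, 6.13% and 6.92%.

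**Figure D1:**
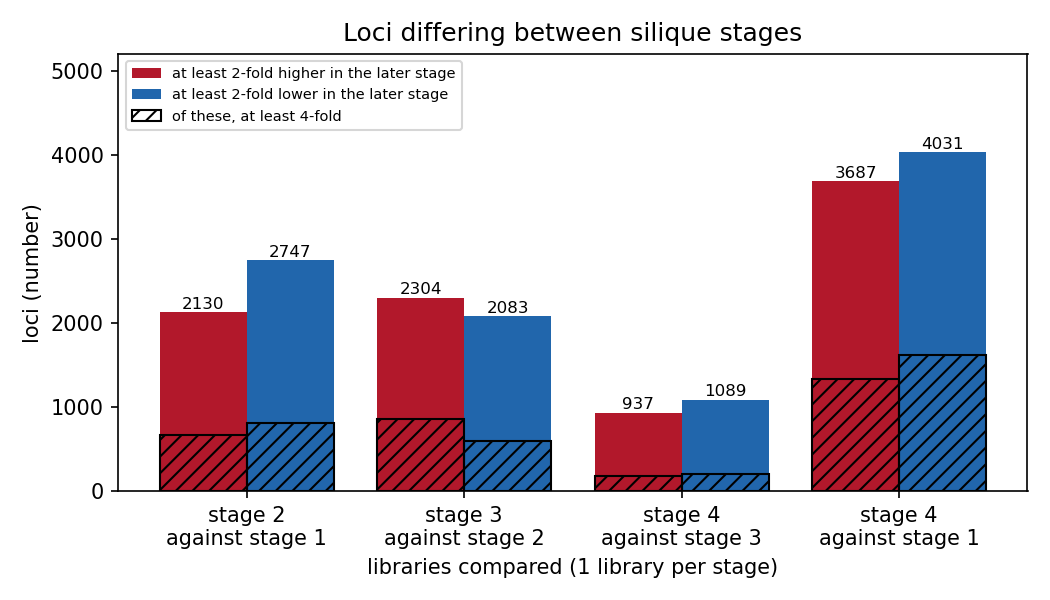
Number of loci whose log2(FPKM + 1) differed by at least 1 between libraries, for each pair of stages compared (x axis), with loci higher in the later stage in red and loci lower in blue; hatching marks those at least 4-fold different. Stage 4 against stage 3 has the lowest bars, 937 higher and 1089 lower, and stage 4 against stage 1 the highest, 3687 higher and 4031 lower.

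Between stage 1 and stage 2 storage, oil body, LEA and maturation regulator genes rose, while pollen genes and, as deposited, expansins fell. All 11 members of the list of 12S globulin and 2S albumin storage proteins were at least 2-fold higher in stage 2, with a median difference of 5.68 on the log2(FPKM + 1) scale. SESA3 stood at 19.4 FPKM in stage 1 and 1070 FPKM in stage 2, and the 12S globulin genes CRA1 and CRC rose from 10.8 to 975 FPKM and from 16.3 to 633 FPKM. Of the 9 oil body genes, 7 were higher (median 4.87), as OLEO1 at 3.63 and 256 FPKM. Of the 23 late embryogenesis abundant (LEA) and desiccation genes, 17 were higher (median 2.89). Each of these 3 medians lay above all those of 10000 random lists matched on expression.

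Regulators of seed maturation were higher in 12 of 17 cases, with a median of 1.84, above all random lists. LEC1, which directs embryo maturation, went from 0.489 to 78.6 FPKM. FUS3 went from 0.152 to 22.1 FPKM and WRI1, an activator of oil synthesis, from 3.61 to 42.1 FPKM. Of 14 endosperm genes, 11 were higher (median 1.44), among them ZOU (0.158 and 24.4 FPKM) and MYB118 (0.115 and 26.9 FPKM). The flavonoid and proanthocyanidin list, which serves seed coat pigment, had 9 of 17 members higher and 1 lower (median 1.08, and 2.1 with equal FPKM sums). BAN, the anthocyanidin reductase, stood at 77.3 and 360 FPKM and TT3, dihydroflavonol reductase, at 34.8 and 237 FPKM. Within the seed coat mucilage list 7 of 18 were higher and 1 lower (median 0.54, percentile 99.8, and 1.74 with equal sums), with the peroxidase PRX36 at 0.154 and 76.6 FPKM. Of 8 heat shock genes, 4 were higher, 1 was lower and 1 was listed at 0 in 1 library (median 1.55, percentile 99.91, and 0.50 with a pseudocount of 5). Abscisic acid genes were higher in 5 of 19 cases and lower in none (median 0.37, within the range of random lists), and their median was 1.32 with equal sums and 0.73 with equal sums over loci of 300 bases or more. The 10 largest increases also held genes outside the lists. AT1G62060, of unknown function, was at 5.02 and 2247 FPKM. The lipid-transfer-like genes AT5G38160 and AT5G38170 reached 3880 and 2635 FPKM from 9.46 and 6.47 FPKM. ENODL3, an early nodulin-like protein gene, went from 1.88 to 676 FPKM.

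In the other direction, 5 of 9 pollen loci were lower in stage 2 and none higher (median -2.27, below all random lists, and -1.48 with equal FPKM sums). AGP6 and AGP11, arabinogalactan proteins of pollen, went from 120 to 3.39 FPKM and from 149 to 4.16 FPKM. Of 11 expansins, wall-loosening proteins of growing cells, 7 were lower as deposited (median -1.26, percentile 0.02). The median was -0.06 with equal FPKM sums, -0.05 without the seed lists in the sums and -0.81 with equal sums over loci of 300 bases or more. The list holds EXPA6 at 281 and 21.6 FPKM. The senescence and chlorophyll breakdown list had 10 of 23 members lower and 3 higher; its median of -0.84 became 0.14 with equal FPKM sums and -0.44 with equal sums over loci of 300 bases or more. SAG12, a cysteine protease used as a senescence marker, fell from 719 to 4.48 FPKM, the largest decrease of this comparison on the log2(FPKM + 1) scale among the genes eligible for naming. Floral organ and nectary genes were lower in 4 of 9 cases and higher in 2 and their median of -0.43, within the range of random lists, became 0.80 with equal sums and 0.03 over the longer loci. The nectary sugar exporter SWEET9 stood at 12.2 and 0.609 FPKM. The stamen and petal identity genes PI and AP3 moved apart, PI from 28.7 to 3.11 FPKM and AP3 from 33.4 to 89.3 FPKM. The median of the photosynthesis list was -0.17 (1.08 with equal sums and 0.30 over the longer loci), with 1 member higher, 3 lower and 25 neither. CAB1 (LHCB1.3) was listed at 0 in stage 1 and 8249 FPKM in stage 2. Cell cycle genes had a median of 0.07 as deposited, with 1 of 34 higher and 3 lower, 1.09 with equal sums and 0.47 over the longer loci.

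Across all loci, 2130 of 17988 compared (11.8%) were at least 2-fold higher in stage 2 and 2747 (15.3%) were lower, a split of 43.7% higher. In the comparisons of stage 3 against 2, 4 against 3 and 4 against 1 the share of higher loci among the changed was 52.5%, 46.2% and 47.8%. As deposited, the median change of all loci was between -0.01 and 0.01 in all 4 comparisons. Scaling to equal FPKM sums put it at 1.05, 0.14, 0.77 and 1.96 in the comparisons of stage 2 against 1, 3 against 2, 4 against 3 and 4 against 1, and the share of higher loci at 92.2%, 60.5%, 91.8% and 93.8%. Leaving the seed storage, oil body and LEA lists out of the sums gave medians of 1.05, 0.22, 0.88 and 2.15 and shares of 92.3%, 64.6%, 94.4% and 94.7%. Both of these sums hold the short locus AT2G01021, which took 78.3% of the deposited FPKM sum in stage 1 and 6.65% in stage 4. Equal sums over loci of 300 bases or more, chosen after seeing the data, gave medians of 0.41, -0.38, 0.05 and 0.12 and shares of 70.3%, 31.7%, 50.5% and 52.8%.

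Between stage 2 and stage 3 the storage, oil body and LEA lists rose further, and the senescence and abscisic acid lists had more members higher than lower. All 23 LEA and desiccation genes were at least 2-fold higher in stage 3, with a median of 5.26. RAB18, a dehydrin, went from 54.0 to 2731 FPKM. Of the storage genes, 7 were higher (median 5.78), SESA1 going from 228 to 16562 FPKM. The other 4 members, CRA1, CRB, CRC and SESA3, were listed at 0 in stages 3 and 4, which in files without counts can be a failed estimate, so no direction is read from them. All 8 oil body genes with a readable value were higher (median 5.29). These medians lay above all random lists. The change in the regulators was smaller, with 8 of 17 higher and 1 lower (median 0.86, and 0.49 with equal sums over loci of 300 bases or more). ABI3, a regulator of dormancy and desiccation tolerance, went from 7.82 to 74.1 FPKM, and the dormancy gene DOG1 from 1.97 to 79.3 FPKM. LEC1 was the regulator that was lower by the 2-fold limit, from 78.6 to 31.6 FPKM.

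The senescence and chlorophyll breakdown list had 15 of 23 members higher and 1 lower (median 1.95, above all random lists). The chlorophyll breakdown genes SGR1 and PPH went from 29.9 to 210 FPKM and from 32.5 to 205 FPKM, and the sugar transporter SWEET15 from 73.6 to 614 FPKM. In the abscisic acid list 10 of 19 were higher and 3 lower (median 1.11, and 1.27 with equal FPKM sums and 0.70 over the longer loci). As deposited this exceeds the 0.37 of stage 2 against 1, while the other 2 scalings gave 1.32 and 0.73 there. NCED6, an enzyme of abscisic acid synthesis, went from 6.47 to 47.1 FPKM. The cold-responsive RD29A declined from 80.6 to 5.44 FPKM. The 10 largest increases included FACT, a fatty alcohol acyltransferase gene, at 0.301 and 209 FPKM, GASA3 at 0.330 and 142 FPKM and EM1, a LEA gene, at 0.780 and 170 FPKM.

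Flavonoid genes had the lowest median of the lists, with 13 of 17 lower and 1 higher (median -2.24, below all random lists). TT3 went from 237 to 20.6 FPKM and BAN from 360 to 42.4 FPKM. The exception was the laccase TT10, which oxidises seed coat flavonoids, at 126 and 388 FPKM. Photosynthesis genes were lower in 13 of 30 cases and higher in none (median -0.94), and cell cycle and DNA replication genes in 14 of 34 cases and higher in none (median -0.75, and -1.15 with equal sums over the longer loci). The replication clamp PCNA1 went from 30.6 to 6.35 FPKM. Among endosperm genes 5 of 14 were lower and 2 higher and the median of -0.17 became 0.05 with equal sums taken without the seed lists and -0.55 with those over the longer loci. The MADS-box genes PHE2 and AGL40 declined from 9.70 to 0.459 FPKM and from 13.3 to 0.237 FPKM. The 10 largest decreases held genes of several kinds. The defensin-like genes AT5G55132 and AT2G21465 went from 296 to 0.476 FPKM, from 154 to 0.0454 FPKM, THI2.1, a thionin, from 640 to 5.82 FPKM and GER3, a germin, from 117 to 0.180 FPKM. In all, 2304 of 17533 loci (13.1%) were higher and 2083 (11.9%) lower, and 150 loci at FPKM 1 or more in stage 2 were listed at 0 in stage 3.

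Between stage 3 and stage 4 late embryogenesis and heat shock genes were among those that rose. As deposited, 937 of 16961 loci (5.5%) were higher and 1089 (6.4%) lower, fewer than between stages 2 and 3. With equal FPKM sums the order of the higher loci turned, with 5178 in stage 4 against 3 and 2848 in stage 3 against 2. Lower loci stayed fewer, at 461 against 1859. Equal sums over loci of 300 bases or more kept both orders, with 1010 higher and 991 lower against 1638 and 3533. Of 23 LEA and desiccation genes 9 were higher and 1 lower (median 0.36, percentile 99.99, and 1.18 with equal FPKM sums and 1.3 without the seed lists in the sums). EM6 (chromosome 2, 16779552 to 16780594) went from 7.54 to 1073 FPKM, EM1 from 170 to 1799 FPKM and M17 from 4.05 to 236 FPKM. Of 8 heat shock genes 6 were higher and none lower (median 1.99, above all random lists, and 3.05 without the seed lists in the sums). From stage 2 to 3 this list had 1 member higher and 2 lower (median -0.46, within the range of random lists). HSP17.4 rose from 31.2 to 789 FPKM and AT5G12030, which encodes another small heat shock protein, from 2.75 to 834 FPKM, without any heat treatment named in the labels. LCR67, a defensin-type peptide gene, showed the largest increase of the named genes, from 5.25 to 3027 FPKM. As deposited, 1 of the 6 readable storage genes was higher (median 0.39), and the median was 1.22 with equal FPKM sums and 1.33 without the seed lists in the sums. That member, SESA5, shares a locus of 168644 bases with a second gene, so its value is uncertain. It stood at 2315 and 10260 FPKM. SESA4, at 10984 FPKM in stage 3, was listed at 0 in stage 4. Oil body genes were higher in 3 of 9 cases (median 0.77, and 1.60 and 1.72 with these sums).

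Cell division genes had the lowest median of the lists, with 25 of 34 lower and none higher (median -1.33, below all random lists). That median was -0.86 without the seed lists in the sums, -0.64 with a pseudocount of 5 and -1.93 with a pseudocount of 0.1. The mitotic syntaxin KN (KNOLLE) went from 79.9 to 15.8 FPKM and the kinase CDKB2;1 from 13.8 to 2.90 FPKM. Lists with smaller medians moved below all or nearly all random lists on the deposited scale. They were photosynthesis (median -0.64, 4 of 30 lower and 1 higher), seed coat mucilage (-0.69, 6 of 18 lower), fatty acid and oil synthesis (-0.39, 2 of 28 lower), secondary wall and lignin (-0.39, 2 of 20 lower and 1 higher) and endosperm (-0.38, 3 of 14 lower and 1 higher). Scaled to equal FPKM sums, these medians were 0.19, 0.11, 0.42, 0.41 and 0.02. With equal sums over loci of 300 bases or more they were -0.57, -0.62, -0.33, -0.32 and -0.33. LCR73, a defensin-type peptide gene, went from 315 to 5.31 FPKM and HEI10, known from meiosis, from 35.3 to 1.33 FPKM.

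From the first to the last stage, storage, oil body, LEA and maturation regulator genes rose and cell cycle genes and expansins fell. All 23 LEA genes (median 8.43), the 6 storage genes with readable values (11.52) and the 8 readable oil body genes (10.24) were higher, as were 15 of 17 regulators of seed maturation (2.76, and 4.43 with equal FPKM sums). SESA2 (chromosome 4, 13609341 to 13610075) had the largest increase among loci of a single gene on the log2(FPKM + 1) scale, 12.90, from 2.55 to 27189 FPKM. Next among them came AT1G47540, a knottin-type peptide gene, at 0.648 and 8608 FPKM, and SESA1 at 2.27 and 16931 FPKM. Abscisic acid genes were higher in 11 of 19 cases and lower in none (median 1.33), and senescence genes higher in 12 of 23 and lower in 2 (median 1.01). With equal FPKM sums these medians were 3.54 and 3.0, and over loci of 300 bases or more 1.45 and 1.11. The regulators differed in timing. LEC1 and LEC2 had their highest values in stage 2, 78.6 and 9.07 FPKM, and stood at 8.00 and 1.84 FPKM in stage 4. FUS3 and ABI3 kept 114 and 81.1 FPKM in stage 4.

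As deposited, 33 of 34 cell cycle genes (median -2.25) and 8 of 11 expansins (median -2.48) were lower at the end. With equal FPKM sums the medians were -0.60 and -1.02, and without the seed lists in the sums -0.45 and -0.89. Neither list had a member that was higher as deposited, the only scaling on which members were counted. The photosynthesis list had 26 of 30 members lower and none higher, and its median of -1.91 became 0.32 with equal FPKM sums and -1.79 with equal sums over loci of 300 bases or more. RBCS1A declined from 14172 to 1928 FPKM and LHCB5, a light-harvesting protein gene, from 2536 to 475 FPKM. The flavonoid list had 11 of 17 lower and 2 higher, with a median of -1.82 that became 0.15 with equal sums and -1.70 with equal sums over the longer loci. The 10 largest decreases included abundant transcripts of stage 1. THI2.1 (chromosome 1, 27198433 to 27199444) went from 2593 to 0.411 FPKM, GER3, a germin, from 1936 to 0.971 FPKM, MLP423 from 2624 to 1.47 FPKM and LP1 from 11558 to 41.5 FPKM. BGLU18, a beta-glucosidase that can release abscisic acid from its conjugate, went from 1580 to 1.26 FPKM. In total 3687 of 17802 loci (20.7%) were higher and 4031 (22.6%) lower in stage 4. The 13 reference genes commonly used for normalisation had a median of -0.06, 2.06 with equal sums and 0.05 over the longer loci, with none higher and 2 lower, ACT2 (382 and 89.1 FPKM) and ACT7 (759 and 311 FPKM).

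**Figure D2:**
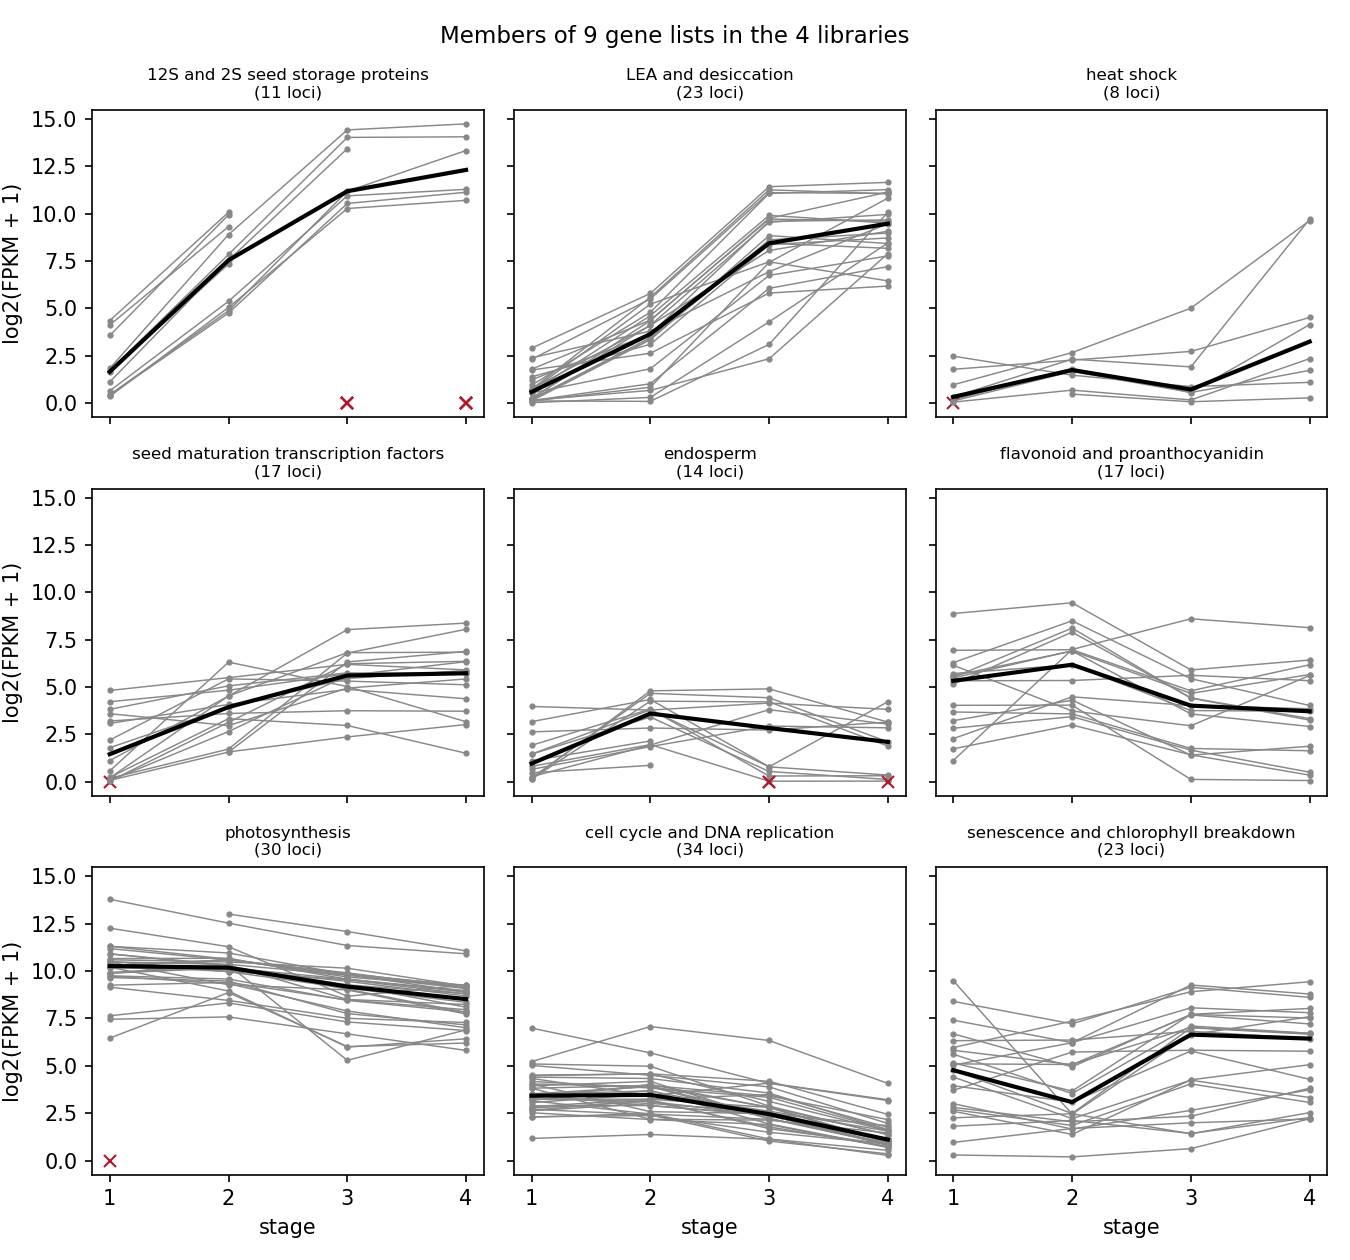
Log2(FPKM + 1) (y axis) of each member (grey lines and points) of 9 gene lists in the libraries of stages 1 to 4 (x axis), with the median over the listed values in black and red crosses for members listed at 0. The storage and LEA medians are lowest in stage 1, the heat shock median is highest in stage 4, and the cell cycle median change from stage 1 to stage 4 is -2.25.

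Genes that peaked in 1 stage, at least 2-fold above each of the other 3 libraries, numbered 1766 for stage 1, 428 for stage 2, 307 for stage 3 and 448 for stage 4, out of 18149 loci with a readable value in all libraries. With equal FPKM sums stage 4 led instead, with 383 loci peaking at stage 1 and 3526 at stage 4, and 362 and 5050 without the seed lists. Both sums hold AT2G01021, which took 78.3% of the deposited FPKM sum in stage 1 and 6.65% in stage 4. Equal sums over loci of 300 bases or more, chosen after seeing the data, kept stage 1 in the lead with 1110 loci, followed by stage 2 with 779. The most abundant peaking genes of stage 1 after AT2G01021 were AT2G40205, a ribosomal protein L41 gene at 20334 FPKM, RBCS1A, LP1 and VSP1, a vegetative storage protein at 5286 FPKM. Stage 2 was led by GILT (AT4G12960), a thiol reductase of the lysosomal type, at 10347 FPKM against 1823, 565 and 119 FPKM in stages 1, 3 and 4. AT4G12870, of the same family, had 1796 FPKM in stage 2. With them peaked the invertase and pectin methylesterase inhibitor-like genes AT1G56100 (2721 FPKM) and AT4G15750 (1456 FPKM) and the gibberellin-regulated GASA1 (984 FPKM). Stage 3 was led by AT5G38160 at 23736 FPKM, which had 9.46 FPKM in stage 1 and 5233 FPKM in stage 4. AT5G38170 lies beside it on chromosome 5 (15227638 to 15228081) and had 7663 FPKM. AT1G62060, AT1G62070 and AT1G62220, uncharacterized genes between bases 22941569 and 22988844 of chromosome 1, followed the same course with 12128, 2815 and 2377 FPKM in stage 3. In stage 4 the list was led by PDF2.1, a defensin gene at 6171 FPKM, AT1G14950 at 4438 FPKM, XTH24, a xyloglucan-modifying enzyme gene, at 2556 FPKM, AT5G45690 at 2550 FPKM and ATS1 (CLO1), a caleosin of oil bodies, at 2328 FPKM.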

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

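The rescaling over loci of 300 bases or more and leaving out loci under 300 bases were chosen after the results were seen, as was leaving loci listed at 0 out of the reported counts; including those at 0 in 1 library is the planned treatment. No paired analysis was possible because each stage has 1 library and its replicate number only names it. Interval overlap could not be used, so leaving it out gives the reported counts, as does dropping the FPKM minimum, and no organelle loci were there to leave out. Of 88 recomputed counts of higher or lower loci, 58 stayed within 1.5 times the reported count, as did 29 of 44 peak counts. Including loci listed at 0 gave 2205 higher and 2868 lower loci in stage 2 against 1 and 2329 and 2233 in 3 against 2. It gave 957 and 1112 in stage 4 against 3 and 3817 and 4439 in stage 4 against 1. Of 261 recomputed list medians for lists that changed by at least 1, 239 moved by less than the spread of members, 18 moved further and 4 changed sign. For lists under 1, 47 of 502 moved further. The spread is the standard deviation over members and can be wide. The expansin median of stage 2 against 1 counts as unmoved, though it went from -1.26 to -0.06 with equal FPKM sums. Some settings could hardly move a result, as dropping the FPKM minimum or median-ratio factors of 0.985 to 1.03. These tallies are therefore no measure of stability. A pseudocount of 5 gave 1092 higher and 1713 lower (stage 2 against 1), 1004 lower (3 against 2), 441 and 542 (4 against 3) and 2351 and 2673 (4 against 1), and 213, 201 and 238 loci peaking at stages 2 to 4. A 4-fold limit gave 676 and 812, 862 and 601, 181 and 209, and 1342 and 1624, with 506, 86, 75 and 86 peaking at stages 1 to 4. Stricter limits and higher pseudocounts count fewer loci by construction. Equal FPKM sums gave 9456 and 798 (2 against 1), 5178 and 461 (4 against 3) and 13779 and 911 (4 against 1), with 383, 172 and 3526 peaking at stages 1, 3 and 4. Without the seed lists in the sums, these were 9456 and 785, 6848 and 404, 14399 and 803, and 362, 162 and 5050. Equal sums over loci of 300 bases or more gave 4053 and 1713 (2 against 1), 3533 lower (3 against 2), and 1110 and 779 peaking at stages 1 and 2. From stage 1 to 4, equal sums and those without the seed lists turned the flavonoid median to 0.15 and 0.35 and the photosynthesis median to 0.32 and 0.52, since they scale stage 4 up against stage 1, while equal sums over loci of 300 bases or more left them at -1.70 and -1.79. They put storage at 13.18 and 13.36, senescence at 3.0 and 3.19, abscisic acid at 3.54 and 3.74 and cell cycle at -0.60 and -0.45. The sums without the seed lists put LEA at 10.06 and cell cycle in stage 4 against 3 at -0.86. A pseudocount of 5 put storage at 9.85, LEA at 6.62 and cell cycle at -1.23 in stage 4 against 1, cell cycle at -0.64 in 4 against 3 and heat shock at 0.50 in 2 against 1. A pseudocount of 0.1 put LEA at 10.15 in stage 4 against 1 and cell cycle at -1.93 in 4 against 3. Storage in stage 3 against 2 was 5.38 with equal sums over longer loci. The storage share in stages 1 to 4 was 0.00456%, 0.440%, 3.45% and 3.83% of FPKM times length and 0.00589%, 0.558%, 6.13% and 6.92% without short loci, in each case without the 4 and 5 members listed at 0 in stages 3 and 4. The share of the 10 most abundant genes, as deposited 80.0%, 65.6%, 53.3% and 19.2%, was 26.9%, 15.8%, 14.0% and 8.73%, and 8.51%, 7.25%, 15.8% and 14.2%. Over loci at FPKM 1 or more in any library, the correlation of stages 1 and 4 was 0.641. Equal FPKM sums and equal sums over loci of 300 bases or more differ almost only by AT2G01021. The other loci under 300 bases held 0.0744% to 0.199% of the deposited FPKM sum of a library. Apart from this, the cause of the differences was not tested beyond what each setting does by construction. With 1 library per stage, depth and replicate spread cannot be separated from stage.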

Other observations

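Of the tests below, the fragment limit, shared reads, ribosomal RNA, floral organ and pollen tests were chosen after the result was seen, and those of real loss and of short loci before it. Some fixed lists had members that went both ways. In the gibberellin list the median was 0.29 from stage 1 to 2, with 8 of 19 higher and 2 lower. It was 1.29 with equal FPKM sums and 0.69 with those over loci of 300 bases or more. From stage 2 to 3 the median was -0.56 (percentile 0.52), with 5 lower and 3 higher. There the same scalings gave -0.45 and -0.88. GA20OX3, a gibberellin synthesis gene, was at 0.448, 111, 279 and 157 FPKM in stages 1 to 4, and GA2OX2, which inactivates gibberellin, at 95.7, 12.6, 3.67 and 4.26 FPKM. From stage 1 to 4 the fruit patterning and dehiscence list had 4 of 21 higher and 2 lower (median 0.00, and 1.76 with equal sums). ADPG1, a polygalacturonase of pod opening, went from 0.913 to 246 FPKM and CEL6, a cellulase, from 124 to 21.2 FPKM. SHP1, which specifies the valve margin, was at 45.0 and 58.0 FPKM.

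Secondary wall and lignin genes were higher in 7 of 20 cases and lower in 2 from stage 1 to 2 (median 0.64, percentile 99.94, and 1.81 with equal sums), with the lignin synthesis gene CCOAOMT1 at 94.3 and 274 FPKM. The xylem protease gene XCP1 went from 23.4 to 1.84 FPKM. The embryo patterning list had 2 of 19 higher and 1 lower from stage 1 to 2 (median 0.08, and 0.64 with equal sums). WOX8 was at 0.285 and 7.90 FPKM and the meristem gene STM at 52.1 and 7.51 FPKM. In the fatty acid list 7 of 28 were higher and 5 lower from stage 1 to 4, with FAE1, which lengthens seed fatty acids, at 0.0398 and 143 FPKM. Its median of -0.13 became 2.07 with equal sums and was -0.01 over loci of 300 bases or more. Of the 3 tapetum genes, 1 was higher in stage 4 than in stage 1, GRP17 at 1.02 and 28.5 FPKM, and the list median of -0.02 became 0.07 with equal sums.

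The storage genes CRA1, CRB, CRC and SESA3 were listed at 0 in stages 3 and 4 while the other storage genes rose. Reads shared between near-identical genes are argued against, since the lowest of the 4 still had 160.0 FPKM (rounded) in stage 2. A limit on fragments per locus may account for CRA1, CRC and SESA3. Carried forward by the median ratio of the listed storage genes, the 4 genes would have had a median of 3.81 times the highest fragment number estimated in stage 3. That number was 811953 (SESA2), and the highest in the other libraries lay between 894709 and 929636. Loci of several genes and very short ones have no estimate. AT2G01021, at 752719 FPKM in stage 3, is among the latter, so a higher fragment number there is not excluded. CRB, projected at 0.893 M, lies above the stage 3 maximum and below those of the other 3 libraries and stays open. Loci outside the storage list were also at 0 in stage 3, as AT5G52080 (330 FPKM in stage 2) and AT5G42223 (109 FPKM). Such a limit was not tested for them. A real loss stays open. Of the 1243 loci with at least 100 FPKM in stage 2, 6 lay at 1 to 10 fragments in stage 3 and 8 at 0. That ratio of 0.75 is within counting error, and the 8 include the 4 storage genes themselves, so it cannot decide for them. The largest readable fall among the 1243 loci was 3380-fold, while the 7 listed storage genes rose. SESA4 in stage 4 stays open too. It was projected at 0.484 times the highest estimate there by the median ratio, and at 1.47 M against 0.895 M fragments by the highest ratio. That ratio, 4.43, is from SESA5, which shares a locus of 168644 bases with a second gene, and the next highest was 1.51. Only this uncertain value puts SESA4 above the highest estimate.

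The AT2G01021 locus, 625 bases past the end of the small ribosomal RNA gene AT2G01020 on chromosome 2, held 78.3% of the FPKM sum in stage 1 and 6.65% in stage 4. A short length that raises every short locus is argued against, since the other loci under 300 bases held 0.199% of the stage 1 sum. Their median above 0 in stage 1 was 2.83 FPKM, against 7.1 for longer loci. This cannot tell how far the short length raised AT2G01021 itself, as the other short loci may have had few reads. Carry-over of ribosomal RNA could not be told apart from other sources. The ribosomal RNA loci examined, those of the small subunit and AT2G01020, stood at 0.0 FPKM in stages 1 and 2. That can be a failed estimate or reads set aside. These loci also do not cover AT2G01021, so ribosomal RNA reads at its own position were not tested. One small-subunit locus, AT3G41768/AT3G41979, was at 480.1 FPKM in stage 4. A difference between stages stays open as untested.

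Pollen genes stood higher in stage 1 than in stage 2, to which their median fell by 2.27. That fall is the pattern itself, so it is no test of pollen on the young fruits, which stays open. Attached floral organs were predicted to leave both petal and stamen identity genes, AP3 and PI, lower in stage 2. That prediction was not met, since AP3 rose by 1.39 on the log2 scale while PI dropped from 28.7 to 3.11 FPKM. As these genes went opposite ways, attached floral organs stay open too. The youngest stage itself was not tested apart from these.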
